A study of Mus musculus with 80 samples.

How the data were processed

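Single cells of the main olfactory epithelium of mice were profiled in droplets. Per the labels' protocols, tissue was dissociated with papain and cells were sorted with DAPI, a dye that marks dead cells. Of the 80 samples of the series, 5 came with processed files, 1 library each of WT, HS5del, HS5inv, ac1pCBSdel and 3xCBS, taken from the genotype labels, and the other 75 were not analysed here. The submitters' processing notes name mm10, Cell Ranger 6.0.1, STAR 2.5.3a, cutadapt 1.9.1, SAMtools 1.3.1, HiC-Pro and Seurat for the series as a whole, without saying which step used which tool. Whether transcripts were captured at their 5′ or 3′ end and how reads in exons shared by several genes were counted are not given in the sources used here.

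The deposited files are unfiltered feature by barcode matrices whose values are counts of unique molecules (UMIs) per gene and barcode, whole numbers that are not normalized. Each has 32285 features and 472217 to 588639 barcodes. No authors' cell annotation was used here, so cell types were rebuilt and a difference from the study's own may come from that. No column of per-sample values was left unused.

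Cells were taken as barcodes with at least 1000 UMIs, at least 500 genes and under 10% mitochondrial UMIs. Scrublet in scanpy 1.11.5 was run per library at an expected rate of 6% and marked 0, 7, 0, 2 and 0 cells in WT, HS5del, HS5inv, ac1pCBSdel and 3xCBS, so it did not work here and doublets are not removed to any useful degree. Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components, 15 neighbours and the Leiden algorithm (igraph 0.11.9) at resolution 1 gave 37 clusters. The clustered Pcdh genes and all genes of the fixed lists other than the cell marker lists were left out of the clustering. So were chemoreceptor, mitochondrial, haemoglobin and sex-linked genes, so that compared genes do not shape the clusters. Some list genes, Rtp1, Adcy3, Cnga4 and Ano2 among them, are also cell markers and helped name the clusters.

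Clusters were named from marker lists fixed before the data were examined. The scoring rule was set after seeing the data. A cluster took the class whose markers had the highest mean standardised expression over clusters, with at least 3 markers in at least 10% of its cells. It stayed unnamed where its 10 leading genes, by ratio to the cells of other classes, held more markers of another class than of its own, or none of its own unless all markers of the class were detected. That last clause named 1 cluster, cluster 5, as mature OSN-like. Clusters 16, 22, 32, 33 and 35 stayed unnamed, with 4, 399, 8, 346 and 11 cells in the libraries in the order above (0.0932%, 12.1%, 0.197%, 5.83% and 0.181%). Cluster 8, sustentacular-like, had a low median of 1498 UMIs. Mature OSN-like cells lay in 11 clusters and immature OSN-like cells in clusters 10 and 13.

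Within mature OSN-like cells UMIs were summed per library, which gave 44549391, 5513080, 44115850, 13376249 and 65551191 UMIs. With 3 counts as the floor, these totals cannot show levels under 0.0673, 0.544, 0.068, 0.224 and 0.0458 counts per 1000000 UMIs (CPM). CPM values carry exact Poisson intervals, ratios the exact conditional binomial interval and shares the exact Clopper-Pearson interval, all at 95% (SciPy 1.17.1), and for a share of 0 the limit given is 3 counts of the total. Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs. Lists were compared as the median log2 ratio over genes with at least 10 UMIs, with a pseudocount of 0.5 UMIs, beside 10000 random lists of the same size drawn from 50 bins of expression.

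For maturation, UMIs were summed per library and class where a library had at least 50 cells of both, which all 5 had. They were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by the quasi-likelihood test with filterByExpr, TMM factors and the library as a block, and gene sets with fry and camera. Both classes of a library come from the same dissociation, which pairs them. Deviations of the 2 classes from their means correlated by 0.265 to 0.346 in the 5 libraries. The libraries differ in genotype, so the result is an average over genotypes, and p-values measure the spread between these 5 libraries. Tested on counts simulated for this comparison over 11909 genes, the procedure recovered 65 of 100 genes changed 2-fold and 95 of 100 changed 4-fold with 9 false calls. The simulation gave every gene the dispersion of the fitted trend and changed only these genes. Real genes spread around that trend (prior degrees of freedom 2.54), and 1568 were called higher and 1500 lower. So these rates need not hold for the real data.

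Gene groups fixed before the data were examined were alternate Pcdha (12 genes), C-type Pcdha (2), Pcdhb (22), alternate Pcdhg (18 in the feature list) and C-type Pcdhg (3), and the lists genes flanking the Pcdh clusters, cohesin and CTCF, DNA methylation and silencing, non-clustered protocadherins, odorant receptor choice, axon guidance and adhesion, dorsal zone, ventral zone, immediate early and dissociation, olfactory transduction, and haemoglobin and erythroid. The rule for named genes was also fixed then. Between genotypes it takes all 14 Pcdha genes, the 2 highest and 2 lowest Pcdhb and Pcdhg ratios among genes with at least 50 UMIs, and, for each library, the 5 genes highest and the 5 lowest against the nearest other library, with at least 100 UMIs and 20 CPM in 1 library, outside chemoreceptor, mitochondrial, haemoglobin, immunoglobulin and sex-linked genes. For maturation it takes clustered Pcdh genes past an adjusted p of 0.05 and up to 4 members of each other list. Omp, Xist and Ddx3y were given outside that rule as checks of the libraries, and Pcdhb1 as the most abundant Pcdhb gene, all chosen after their values were seen.

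The alternatives tried were other limits on UMIs and mitochondrial share, doublets kept, cells of highest doublet score left out, mature cells by Omp, Gap43 and Gng8 UMIs, TMM scaling, totals without mitochondrial and receptor genes, a mean over cells, subtraction of the profile of barcodes with 10 to 100 UMIs, the median of the other mutants as the reference, shared clusters weighted equally, other thinning depths, DESeq2 1.42.0 and its size factors, no filter on low counts, no block, each library left out, each immature cluster alone, and the libraries of mixed or mostly neuronal cells alone. Coordinates come from GENCODE M21 and RefSeq annotations of the mm10 build.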

Results

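The series profiled the olfactory epithelium of mice, the nasal tissue that holds the olfactory sensory neurons (OSNs), and its title concerns how cohesin, the ring complex that extrudes chromatin loops, acts on the clustered protocadherin genes. Of its 80 samples, 5 were analysed here, each a droplet single-cell RNA library of 1 genotype, and the other 75 were not analysed here. Clustered protocadherins (Pcdh) are cell surface adhesion proteins that mark single neurons, and their genes lie in the adjoining Pcdha, Pcdhb and Pcdhg arrays. All 5 genotype labels hold Omp_GFP, a tag of the Omp gene by its name, and that of WT holds nothing else. The 4 mutant libraries were further labelled HS5-1del/del (HS5del), HS5-1inv/inv (HS5inv), ac1pCBSdel/del (ac1pCBSdel) and 3xCBS/3xCBS (3xCBS). HS5-1 is known as an enhancer of the Pcdha array, and the sources used here do not spell out the other labels. The altered elements are not genes in the feature list, so no count of a target gene could check a label. With 1 library per genotype there was no replicate, and no test between genotypes was possible. All intervals between genotypes are 95% intervals that cover counting error only. They are exact except those of the effective number of genes, which come from resampling.

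The libraries held 55537346 UMIs in WT, 49528998 in HS5del, 50567086 in HS5inv, 45372001 in ac1pCBSdel and 74742088 in 3xCBS. After filtering, 4294, 3297, 4053, 5933 and 6085 cells were left in that order, which held 94.2%, 60.2%, 92.9%, 76.7% and 91.1% of the UMIs. The libraries fell apart by cell type. Mature OSN-like cells, which express the signalling genes of odour transduction, made up 88.2% of WT cells (95% exact binomial interval 87.2 to 89.2), 95.6% of HS5inv (94.9 to 96.2) and 96.9% of 3xCBS (96.5 to 97.4), but 22.5% of HS5del (21.1 to 24.0) and 40.9% of ac1pCBSdel (39.6 to 42.1). Sustentacular-like cells, the supporting cells of the epithelium, made up 21.9% of HS5del (20.5 to 23.3) and 14.1% of ac1pCBSdel (13.2 to 15.0), and at most 0.326% of the other libraries. Immature OSN-like cells ranged from 1.91% in 3xCBS to 10.6% in WT. This class was unstable, so neither the range nor the order of libraries is firm. With the marked doublets kept and cells clustered anew, such cells went from 455 to 200 in WT and from 116 to 52 in 3xCBS. In HS5del they went from 260 to 230. The titles call WT, HS5inv and 3xCBS OSN samples and HS5del and ac1pCBSdel OE samples, though the deposited data of ac1pCBSdel are named OSN, and cells were sorted per the labels' protocols. The shares go with the titles and are not read as effects of genotype.

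The libraries also differed in ways that the labels do not give or explain. HS5del had 19.4 counts per 1000000 UMIs (CPM) of the Y-linked gene Ddx3y in mature OSN-like cells and 0.181 of Xist, the RNA of the inactive X. The other 4 libraries had 0 UMIs of Ddx3y and 216 to 333 CPM of Xist. Omp, the olfactory marker protein gene, stood at 5658, 5592 and 5361 CPM in WT, HS5inv and 3xCBS but at 800 CPM in HS5del and 1128 in ac1pCBSdel. Whether Omp_GFP replaces an Omp copy, and in how many copies each library carried it, is not given in the sources used here and was not tested, and it bears on Omp levels and on classes taken by Omp UMIs. The title of the WT library has a tag (mus_cas) that no mutant library has. Its meaning is not given in the sources used here, and a hybrid strain would bear on read mapping and so on the ratios to WT. Mature cells lay in different clusters by library: clusters 0 and 4 held 49.7% and 29.8% of the WT cells, cluster 25 held 69.9% of HS5del, clusters 7, 2 and 3 held 26.6%, 24.6% and 20.1% of HS5inv, clusters 1 and 7 held 28.1% and 24.1% of ac1pCBSdel, and clusters 7 and 3 held 34.8% and 19.6% of 3xCBS. These facts stand beside each comparison of mature cells that follows.

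The first question was how the clustered Pcdh genes were transcribed in mature neurons without the HS5-1 element as labelled in HS5del. The 12 alternate Pcdha genes, the variable part of the array from which neurons draw, summed to 17.8 CPM (14.4 to 21.7) in HS5del against 98.1 CPM (95.2 to 101.0) in WT, a ratio of 0.181 (0.147 to 0.221). All 12 genes were lower, with ratios from 0.0548 for Pcdha11 to 0.5 for Pcdha3 and a median of 0.188. Pcdhac2, the C-type gene at the far end of the array, was higher, at 31.9 CPM (27.4 to 37.0) against 9.27 (8.40 to 10.2), a ratio of 3.44 (2.87 to 4.12). The Pcdhb genes as a group were lower, at 201 against 257 CPM and a ratio of 0.782 (0.734 to 0.831), and the alternate Pcdhg genes were higher, at 58.6 against 47.9 CPM and a ratio of 1.22 (1.08 to 1.38). The most abundant Pcdhb gene, Pcdhb1, was at 120.8 CPM against 156.2.

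Single Pcdhb genes in HS5del went both ways, 5 higher and 14 lower of the 19 with at least 50 UMIs in both libraries together. Pcdhb9 was lowest, at 0.187 of WT (0.0989 to 0.322), followed by Pcdhb5 at 0.234 (0.0629 to 0.613). Pcdhb11 was highest, at 5.26 times WT (3.69 to 7.45), followed by Pcdhb3 at 4.25 (2.66 to 6.67). Of 16 alternate Pcdhg genes 12 were higher, 4 with intervals above 1, led by Pcdhga8 at 2.33 (1.22 to 4.20) and Pcdhga3 at 1.78 (1.19 to 2.60). The lowest was Pcdhgb7 at 0.526 (0.222 to 1.07), with Pcdhgc3, a C-type gene, at 0.465 (0.197 to 0.942). Pcdhac1 stood at 6.17 CPM against 3.91, a ratio of 1.58 (1.06 to 2.29) from 34 UMIs, which turned to 0.714 where mature cells were taken by marker UMIs, Omp among them although it is low in HS5del, and was 2.75 over the median of the other 3 mutant libraries. Over that median the alternate Pcdhg ratio turned to 0.81. Weighting shared clusters equally, an alternative chosen after seeing the data, gave 5.43 for Pcdhac2 and 2.59 for Pcdhac1. These were clusters 0, 1, 2 and 7, with 24, 43, 50 and 26 HS5del cells, and left out cluster 25 with 69.9% of them. The HS5del cells there held 6, 9, 15 and 0 UMIs of Pcdhac2 and 3, 1, 1 and 1 of Pcdhac1, so both values are weakly based.

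In HS5inv the same questions were asked of HS5-1 as labelled inv/inv. The alternate Pcdha genes summed to 35.8 CPM (34.1 to 37.6), a ratio to WT of 0.365 (0.345 to 0.387). All 12 were lower. The highest ratios were those of Pcdha1 at 0.676 (0.598 to 0.764), Pcdha8 at 0.648 (0.449 to 0.930) and Pcdha3 at 0.578 (0.486 to 0.686), and the lowest those of Pcdha6 at 0.0946 (0.0618 to 0.140) and Pcdha12 at 0.114 (0.0733 to 0.169). Pcdhac2 was at 33.3 CPM (31.6 to 35.0), a ratio of 3.59 (3.21 to 4.01), and Pcdhac1 was lower, at 2.24 CPM and a ratio of 0.575 (0.444 to 0.740). The Pcdhb genes were higher as a group, at 374 CPM and a ratio of 1.46 (1.42 to 1.49), with 16 of 21 single genes higher, and the alternate Pcdhg genes were at 65.3 CPM, a ratio of 1.36 (1.29 to 1.44), with 13 of 17 higher and 7 intervals above 1.

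The highest Pcdhb ratios in HS5inv were those of Pcdhb2 at 4.63 (2.45 to 9.50) and Pcdhb11 at 3.51 (2.75 to 4.52), and the lowest those of Pcdhb18 at 0.515 (0.385 to 0.683) and Pcdhb9 at 0.575 (0.500 to 0.661). Pcdhgb6 was at 3.17 (2.54 to 3.98) and Pcdhga3 at 2.01 (1.65 to 2.46), while Pcdhgb7 was at 0.624 (0.463 to 0.837) and Pcdhga12 at 0.805 (0.624 to 1.04). Against the median of the other 3 mutants the alternate Pcdhg ratio turned to 0.903 and the Pcdhac1 ratio was 0.364.

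In ac1pCBSdel the C-type Pcdha genes were both lower than in WT. Pcdhac1 was at 0.523 CPM (7 UMIs, 0.210 to 1.08), a ratio of 0.134 (0.0531 to 0.282), and Pcdhac2 at 3.59 CPM, a ratio of 0.387 (0.281 to 0.523). Pcdha12, the last alternate gene before Pcdhac1, was higher, at 22.4 CPM (20 to 25.1) against 5.39 and a ratio of 4.16 (3.50 to 4.95). The other 11 alternate genes ranged from 0.282 for Pcdha5 to 1.06 for Pcdha3, and the 12 together were at 87.1 CPM, a ratio of 0.888 (0.832 to 0.947). The Pcdhb group was at 249.5 CPM, a ratio of 0.969 whose interval (0.932 to 1.01) includes 1. Pcdhb1 gave 1976 of its 3337 UMIs, and single genes went both ways. Of 19 measured, 11 were higher (5 intervals above 1) and 8 lower (8 intervals below 1). The alternate Pcdhg group was at 72.3 CPM, a ratio of 1.51 (1.40 to 1.63), with 15 of 17 genes higher and 6 intervals above 1.

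Single genes in ac1pCBSdel again included Pcdhb9, at 0.261 of WT (0.187 to 0.355), and Pcdhb6, at 0.235 (0.115 to 0.432). Pcdhb14 was at 2.01 (1.67 to 2.40) and Pcdhb11 at 1.78 (1.22 to 2.58). Pcdhga2 was at 6.42 (4.00 to 10.5) and Pcdhgb6 at 3.49 (2.65 to 4.59), while Pcdhgc3 was at 0.503 (0.302 to 0.8) and Pcdhgb5 at 0.712 (0.467 to 1.05). Over the median of the other 3 mutants the alternate Pcdha ratio turned to 2.43 and that of Pcdhac2 was 0.112. With shared clusters weighted equally the C-type Pcdhg ratio moved from 0.886 to 0.576. Against HS5del, the other library of mixed cell types, ac1pCBSdel had 4.90 times the alternate Pcdha level (3.98 to 6.08), 0.0849 times that of Pcdhac1 (0.0317 to 0.194) and 0.112 times that of Pcdhac2 (0.0799 to 0.155).

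In 3xCBS the last 3 alternate Pcdha genes were far lower than the first. Pcdha1, Pcdha3 and Pcdha7 were at 1.06 (0.958 to 1.17), 1.16 (1.02 to 1.33) and 1.03 times WT (0.858 to 1.23). Pcdha5, Pcdha6 and Pcdha9 were at 0.548, 0.525 and 0.547, Pcdha10 at 0.263 (0.203 to 0.338), Pcdha11 at 0.233 (0.184 to 0.293) and Pcdha12 at 0.0934 (0.0629 to 0.135). The group was at 69.7 CPM, a ratio of 0.711 (0.682 to 0.741). Pcdhac1 was higher, at 8.21 CPM and a ratio of 2.10 (1.77 to 2.51), and Pcdhac2 was at 10.9 CPM, a ratio of 1.17 (1.04 to 1.33). The Pcdhb genes were at 384 CPM, a ratio of 1.49 (1.46 to 1.53), and the alternate Pcdhg genes at 93.2 CPM, a ratio of 1.94 (1.85 to 2.04), with all 17 genes measured higher and 13 intervals above 1. Part of this may lie in the mix of cells. Cluster 9 held 6.98% of mature 3xCBS cells, 3.95% of HS5inv and 0.739% of WT. It had 1010 CPM of Pcdhb and 333 of alternate Pcdhg in 3xCBS, and 830 and 181 in WT. With shared clusters weighted equally the 3xCBS ratios were 1.22 and 1.59. Clusters 1, 7 and 9 held 34, 24 and 28 WT cells, with 12, 10 and 19 UMIs of alternate Pcdhg. Both ratios are thus weakly based on the WT side.

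Pcdhgb6 was at 3.81 times WT in 3xCBS (3.10 to 4.73) and Pcdhga2 at 4.39 (2.94 to 6.80), while the lowest Pcdhg ratios, Pcdhgc4 at 0.929 (0.566 to 1.54) and Pcdhgc3 at 1.01 (0.808 to 1.26), had intervals that include 1. Pcdhb2 was at 2.49 (1.29 to 5.18), Pcdhb16 at 2.23 (1.91 to 2.60), Pcdhb6 at 0.518 (0.405 to 0.662) and Pcdhb5 at 0.601 (0.467 to 0.772). Over the median of the other 3 mutants the alternate Pcdha ratio turned to 1.95 and the Pcdhac2 ratio to 0.34, and that of Pcdhac1 was 3.66. The C-type Pcdhg genes as a group stood at 4.22, 3.27, 4.06, 3.74 and 4.00 CPM in WT, HS5del, HS5inv, ac1pCBSdel and 3xCBS, and all 4 intervals of the ratio include 1. Some shifts were common to all 4 mutant libraries. Alternate Pcdhg lay above WT (1.22, 1.36, 1.51 and 1.94) and alternate Pcdha below it (0.181, 0.365, 0.888 and 0.711). Pcdhb11 lay above WT (5.26, 3.51, 1.78 and 1.72) and Pcdhb9 below it (0.187, 0.575, 0.261 and 0.876). What all mutants share cannot be told apart from a trait of the WT library.

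**Figure D1:**
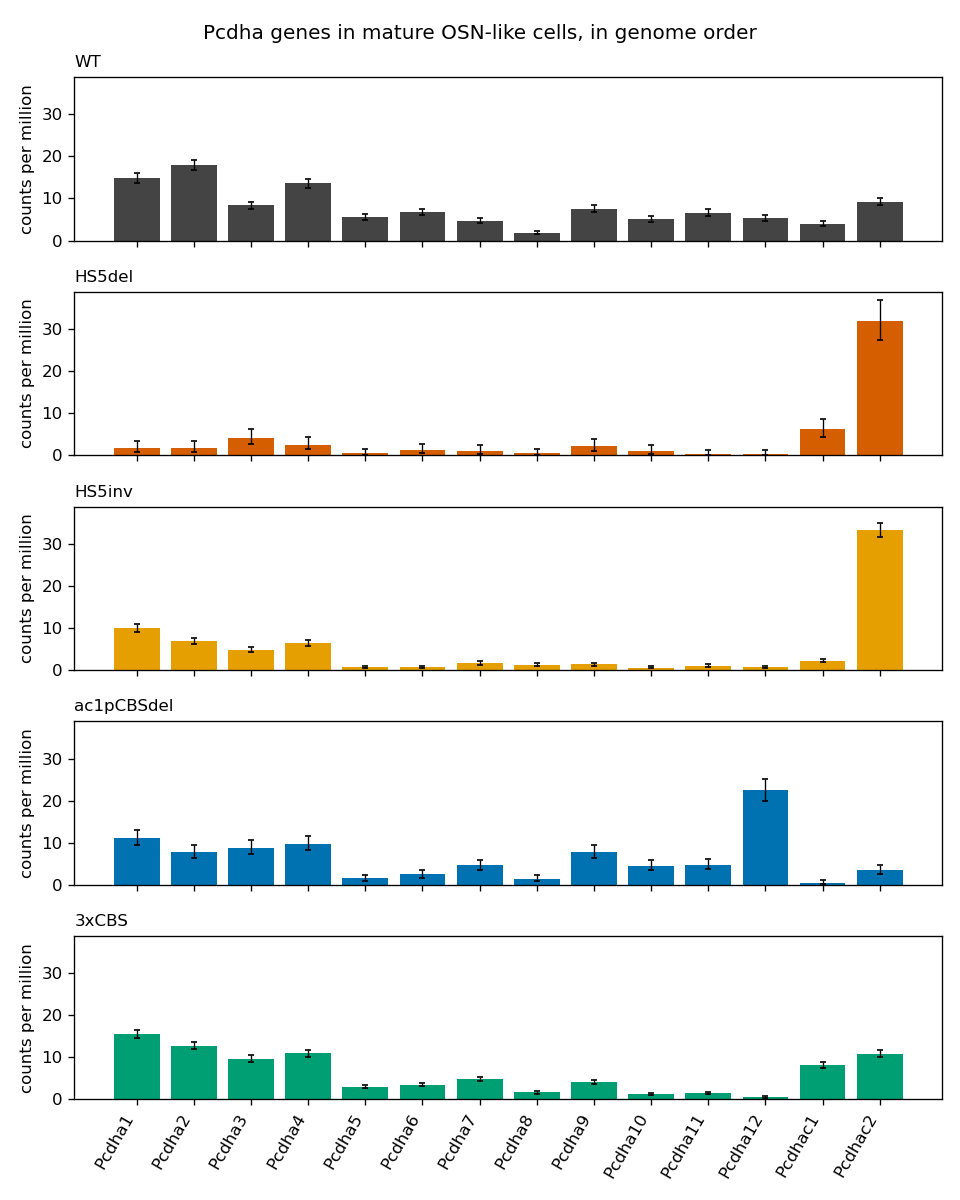
CPM of each Pcdha gene in mature OSN-like cells, 1 panel per library (1 library per genotype), genes in genome order. Bars are the level and error bars the exact Poisson interval (counting error). Pcdhac2 stands at 31.9 and 33.3 in HS5del and HS5inv, Pcdha12 at 22.4 in ac1pCBSdel, and Pcdha10 to Pcdha12 are low in 3xCBS.

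**Figure D2:**
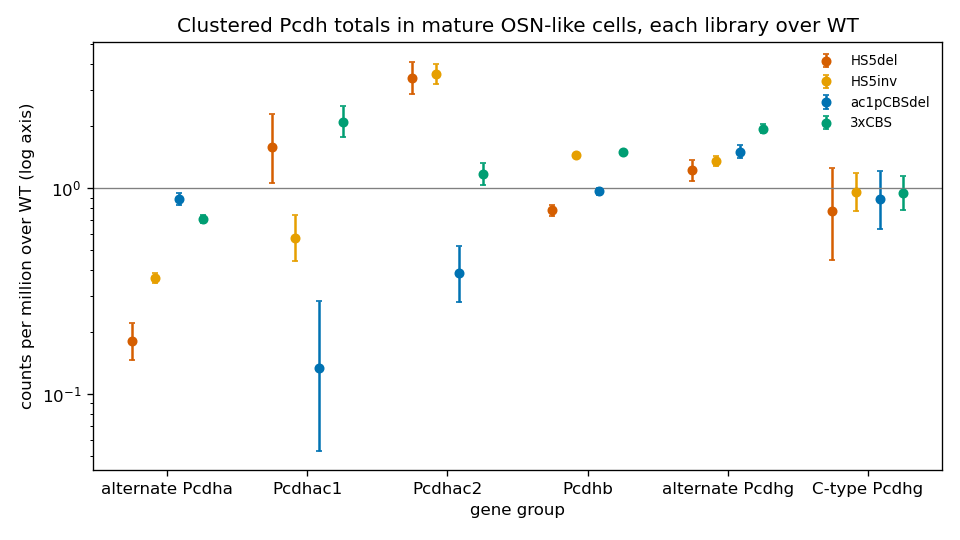
Ratio of the summed CPM of each Pcdh gene group in mature OSN-like cells to that of the WT library, on a log axis, 1 point per mutant library. Error bars are exact conditional binomial intervals (counting error). Alternate Pcdha lies under 1 in all 4 libraries, from 0.181 in HS5del to 0.888 in ac1pCBSdel.

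In the genome build mm10 these genes lie on the plus strand of chromosome 18. The alternate Pcdha genes start between 36930184 (Pcdha1) and 37020149 (Pcdha12), Pcdhac1 starts at 37090013 and Pcdhac2 at 37143503. Their annotated models run to 37187657 or 37187661, since each variable first exon is spliced to the same constant exons. Pcdhb1 spans 37264938 to 37267525. The feature list names Pcdha11 under 2 identifiers. The model that starts at 37005203 matched Pcdha10 of RefSeq by position, the one at 37010712 matched Pcdha11, and they are named so here. How reads in constant exons were assigned is not given in the sources used here, so levels of single Pcdha and Pcdhg genes are uncertain by that much.

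The spread of UMIs over the alternate Pcdha genes was described next. WT had the highest effective number, 10.4 genes (exponential of the Shannon entropy, 10.2 to 10.5 by multinomial resampling). It was 9.43 in HS5del (7.65 to 10.1), 7.5 in HS5inv (7.16 to 7.79), 9.3 in ac1pCBSdel (8.9 to 9.61) and 8.48 in 3xCBS (8.3 to 8.65). Drawn to the 98 UMIs of HS5del, the numbers were 9.81, 9.43, 7.11, 8.85 and 8.03. These have no interval, and the number falls with fewer UMIs, so WT is not shown to be more even than HS5del. The leading gene was Pcdha2 in WT (18.3% of the alternate UMIs), Pcdha3 in HS5del (23.5%), Pcdha12 in ac1pCBSdel (25.8%) and Pcdha1 in HS5inv and 3xCBS (27.9% and 22.4%). Pcdha10, Pcdha11 and Pcdha12 together gave 17.4% in WT, 10.2% in HS5del, 6.07% in HS5inv, 36.4% in ac1pCBSdel and 4.84% in 3xCBS.

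Fewer single neurons of HS5del and HS5inv than of WT held an alternate Pcdha UMI. After each cell was thinned to 2000 UMIs, the share was 17.8% of 3767 WT cells (16.6 to 19.1), 3.05% of 722 HS5del cells (1.92 to 4.58), 6.96% of 3808 HS5inv cells (6.17 to 7.81), 16.5% of 2381 ac1pCBSdel cells (15.1 to 18.1) and 13.7% of 5879 3xCBS cells (12.9 to 14.6). Unthinned, at median depths of 11334, 7333, 11191, 5460 and 10763 UMIs, the shares were 63.2%, 12%, 30.7%, 35.8% and 49.3%. Thinning left out 22, 21, 67, 43 and 20 shallower cells. A Pcdhac2 UMI was seen in 1.73%, 7.06%, 6.41%, 0.84% and 2.09% of the thinned cells and a Pcdhac1 UMI in 0.77%, 1.25%, 0.578%, 0.084% and 1.63%. Any clustered Pcdh UMI was seen in 55.5%, 46.5%, 61.4%, 54.8% and 65.0%. At this depth 1.14% of WT cells (0.827 to 1.53) held UMIs of 2 or more alternate Pcdha genes, against 1.48% with genes shuffled across cells. The shares were 0.21% in HS5inv (0.219% shuffled), 1.18% in ac1pCBSdel (1.23%) and 0.782% in 3xCBS (0.848%), and 0 of 722 cells in HS5del (0.0325%), which by 3 counts of the total allows up to 0.416%. Unthinned, the share was 20.6% in WT (19.3 to 21.9) against 21.6% shuffled, and in 3xCBS 11.3% (10.5 to 12.1) against 12.3%, which lies above the interval.

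Sustentacular-like cells served as background where at least 50 were present. In HS5del 0.579% of 518 such cells held an alternate Pcdha UMI (0.120 to 1.68, median 14097 UMIs, 203 shallower cells left out), and in ac1pCBSdel 1.78% of 729 cells (0.953 to 3.03, median 7779 UMIs, 107 left out), both below the mature neurons of the same library, whose retained cells had medians of 7424 and 5489 UMIs. A Pcdhac2 UMI was seen in 5.02% and 4.53% of them, so for Pcdhac2 these cells are no background. For Pcdhac1 the background was 0.386% in HS5del (0.0468 to 1.39), whose interval overlaps that of the neurons (0.572 to 2.35), and 0 of 729 in ac1pCBSdel, which allows up to 0.412%. WT, HS5inv and 3xCBS had 14, 4 and 9 sustentacular-like cells and no such background. Scaled by sustentacular markers, the profile of near-empty barcodes made up 7.41%, 28.4% and 23.1% of the mature UMIs in these 3 libraries, 4.63% in HS5del and 3.24% in ac1pCBSdel, and no share of cells was corrected for it.

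**Figure D3:**
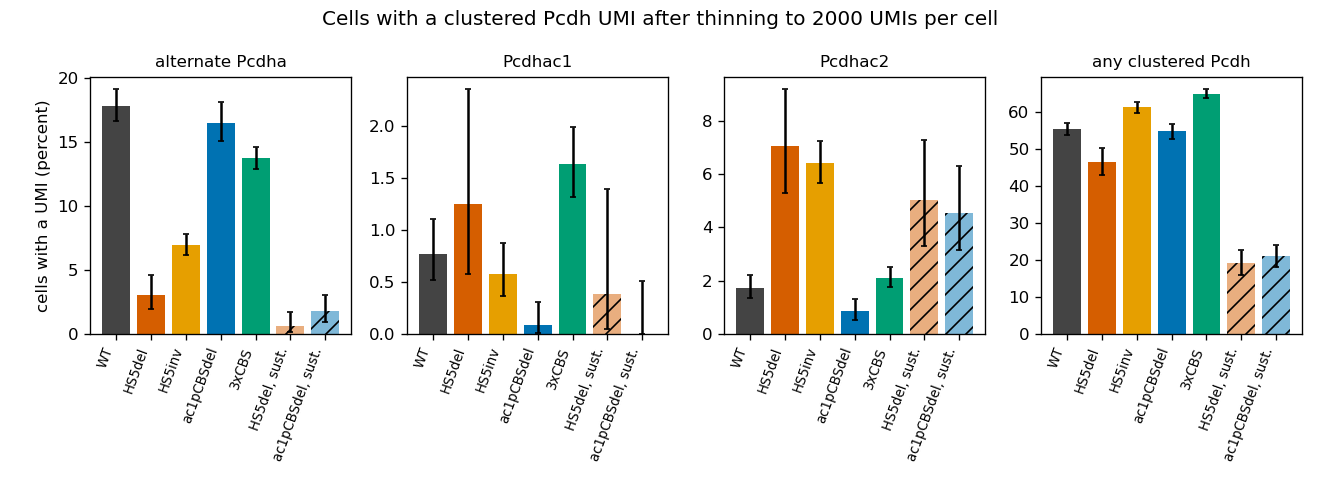
Percent of cells with at least 1 UMI of each Pcdh group after thinning to 2000 UMIs per cell, for mature OSN-like cells of the 5 libraries (plain bars) and sustentacular-like cells (sust.) of the HS5del and ac1pCBSdel libraries (hatched bars). Error bars are exact binomial intervals (counting error). For alternate Pcdha, WT stands at 17.8% and HS5del at 3.05%.

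Gene lists fixed before the data were examined were compared between each mutant and WT as the median log2 ratio, with its percentile among 10000 random lists matched on size and expression. The dorsal zone list, 3 genes of the dorsal epithelium, was low in HS5del (−1.17, percentile 0.03) and ac1pCBSdel (−0.73, 0.21) and high in HS5inv (0.48, 98.3) and 3xCBS (0.53, 99.0). The ventral zone list, 4 genes, stood at 0.46 (99.8) in HS5del, −0.17 (10.4) in HS5inv, 0.73 (99.9) in ac1pCBSdel and 0.09 (52.3) in 3xCBS. Markers of sustentacular cells were high within mature neurons of HS5del (2.57) and ac1pCBSdel (3.11), above all 10000 random lists, and stood at −0.29 in HS5inv and −0.79 in 3xCBS. Haemoglobin and erythroid genes went from −5.55 in HS5inv and −5.01 in ac1pCBSdel to 1.37 in 3xCBS and 3.14 in HS5del. The median of all genes lay between −0.01 and 0.05.

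Lists of neuronal state were compared in the same way. Immediate early and dissociation genes were low in HS5del (−0.35, percentile 0.05), ac1pCBSdel (−0.38, 0.04) and 3xCBS (−0.67, below all random lists) and stood at −0.01 (36.7) in HS5inv. Olfactory transduction genes stood at 0.29 (99.8) in HS5inv and 0.27 (99.6) in 3xCBS, against −0.06 (20.3) in HS5del and 0.05 (55.7) in ac1pCBSdel, and the mature OSN markers at 0.36, 0.31, −0.05 and 0.04 in the same order. Immature OSN markers were low in HS5del (−0.46), HS5inv (−0.47), ac1pCBSdel (−0.79) and 3xCBS (−0.38), with percentiles of 0.33 or less. Odorant receptor choice genes stood at 0.22 (97.6) in HS5inv, 0.24 (98.2) in 3xCBS, −0.11 (12.7) in HS5del and 0.03 (56.2) in ac1pCBSdel. Cohesin and CTCF genes, which build and anchor loops, had medians of 0.05 to 0.24 in HS5del, HS5inv and 3xCBS and of 0.00 in ac1pCBSdel, at percentiles from 56.0 to 90.7, and DNA methylation and silencing genes medians from −0.06 to 0.04, at 15.9 to 46.0. Axon guidance and adhesion genes had medians from −0.07 to 0.08, at percentiles 18.1 to 53.7. Genes flanking the Pcdh clusters stood at 0.20 (95.3) in HS5del, 0.05 (39.5) in HS5inv, 0.13 (93.0) in ac1pCBSdel and 0.02 (30.2) in 3xCBS, and non-clustered protocadherins at −0.17 (6.73), 0.00 (21.5), −0.32 (0.76) and 0.18 (71.6) in that order.

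The Pcdh groups were also placed among random lists. The alternate Pcdha median was −2.34 (percentile 0.07) in HS5del, −1.99 (0.02) in HS5inv, −0.37 (5.16) in ac1pCBSdel and −0.68 (0.58) in 3xCBS. The Pcdhb median was −0.42 (1.91), 0.39 (99.2), 0.10 (67.4) and 0.42 (99.8). The alternate Pcdhg median was 0.30 (83.5), 0.37 (97.4), 0.34 (91.4) and 0.94, above all random lists, with 18 of 18 genes higher in 3xCBS. The C-type lists have few genes, and their medians lay within percentiles 13 to 92.7 for Pcdha and 47.8 to 79.7 for Pcdhg.

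Single genes that set a library apart were named by a rule of size. Mmel1, a membrane metallopeptidase, was at 308 CPM in WT and at most 6.28 in the mutants, and Gstm7, a glutathione transferase, at 52.7 against at most 1.09, with Tgfb2, Naprt and Tuba1c at 59.1, 20.1 and 23.5 against at most 1.64. Lowest in WT were 2610035D17Rik (0.786 CPM against 20.9 or more), Bpifa1, Dmd, Clmn and the ribosomal protein gene Rps18 (53.9 against 246 or more). In HS5del the highest were secreted lipocalins and odorant-binding proteins of nasal glands, Lcn3 (567 CPM), Lcn4 (230), Obp2b (1425) and Obp2a (2353, against 3.36 or less), and Dmbt1 (34.1). They stand beside the high sustentacular markers of that library and a Bowman gland-like share of 3.12% of its cells. The lowest in HS5del were Sqor (1.63 CPM against 31.9 or more), Gm13762 (0 UMIs), Spint1, Scpep1 and S100z.

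In HS5inv the highest were 4930516K23Rik (72.1 CPM), Vcpkmt, Matn2, Glo1 (387 against 242 or less) and Gm8797, and the lowest Mobp, Gm47283, Eps8l1, Isoc2a and Ptprz1 (3.49 against 14.7 or more). In ac1pCBSdel the highest were Gm31557 (50.9), Gm3896, S100a10, Resp18 and Chil4, and the lowest Mbl2, Hist3h2ba, Insm1, a transcription factor of developing neurons (2.47 against 7.44 or more), Rsph3a and Pcdhac2. In 3xCBS the highest were Gm21887 (174), Gm49542, Gm47283, the non-clustered protocadherin Pcdh8 (91.6 against 51.7 or less) and Pdlim1, and the lowest Gm10260 (0.107 CPM against 126 or more), BC023719 (0 UMIs, at least 433-fold lower against the floor), Hist2h2ac, Obp2a and Wfdc18.

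The maturation of OSNs was the only comparison with replicates: mature minus immature OSN-like cells, summed per library, with the library as a block (n = 5 libraries of different genotypes). The classes came from clustering the same cells, which favours genes that part them, but the Pcdh genes and the other fixed lists, cell markers aside, were left out of the clustering. Of 12090 genes tested, 1568 were higher and 1500 lower in mature cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among 46 clustered Pcdh genes tested, Pcdhb1 rose by 0.92 log2 (SE 0.203, adjusted p = 0.0231, higher in 5 of 5 libraries), Pcdhac2 fell by 1.34 (SE 0.292, adjusted p = 0.0224, lower in 5 of 5) and Pcdhb9 fell by 1.42 (SE 0.371, adjusted p = 0.0367, lower in 4 of 5). None of the 46 passed when adjusted over the list alone, where at an unadjusted p under 0.05 there were 2 higher and 6 lower, and DESeq2 called 6 over all genes. No list of Pcdh genes passed camera: the adjusted p was 0.492 for alternate Pcdha, 0.328 for C-type Pcdha, 0.988 for Pcdhb and 0.793 for alternate Pcdhg. The mixed test of fry, which asks whether genes of a set change in either direction, gave an adjusted p of 0.000689 over all 46.

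The Pcdh calls lay near the threshold, and leaving out a library ended some while the change kept its direction, from 0.76 to 1.03 log2 for Pcdhb1, from −1.55 to −1.09 for Pcdhac2 and from −1.67 to −1.16 for Pcdhb9. Without 3xCBS the adjusted p was 0.0558 for Pcdhb1, 0.0734 for Pcdhac2 and 0.11 for Pcdhb9. For Pcdhb1 it was 0.0607 without HS5del and 0.0581 without ac1pCBSdel, and for Pcdhb9 0.0995 without HS5inv and 0.101 without ac1pCBSdel. Without the block all 3 calls were lost (adjusted p = 0.173, 0.197 and 0.126), and in cells thinned to 2000 UMIs those of Pcdhac2 (0.0514) and Pcdhb9 (0.0799). The immature class lay mostly in cluster 10 in WT, HS5inv and 3xCBS (92.7%, 90.7% and 87.1% of its cells) and mostly in cluster 13 in HS5del and ac1pCBSdel (72.7% and 70.5%). In alternatives added after seeing the data, Pcdhb1 rose by 0.37 log2 over cluster 10 alone (4 libraries) and by 3.04 over cluster 13 alone (2 libraries). With classes by marker UMIs, chosen before the data were seen, it rose by 3.05 (2 libraries). The count of genes higher in mature cells was 920 without HS5del, 766 without HS5inv, 565 without ac1pCBSdel and 429 without 3xCBS, and that of lower genes 924, 793 and 665 without the last 3.

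**Figure D4:**
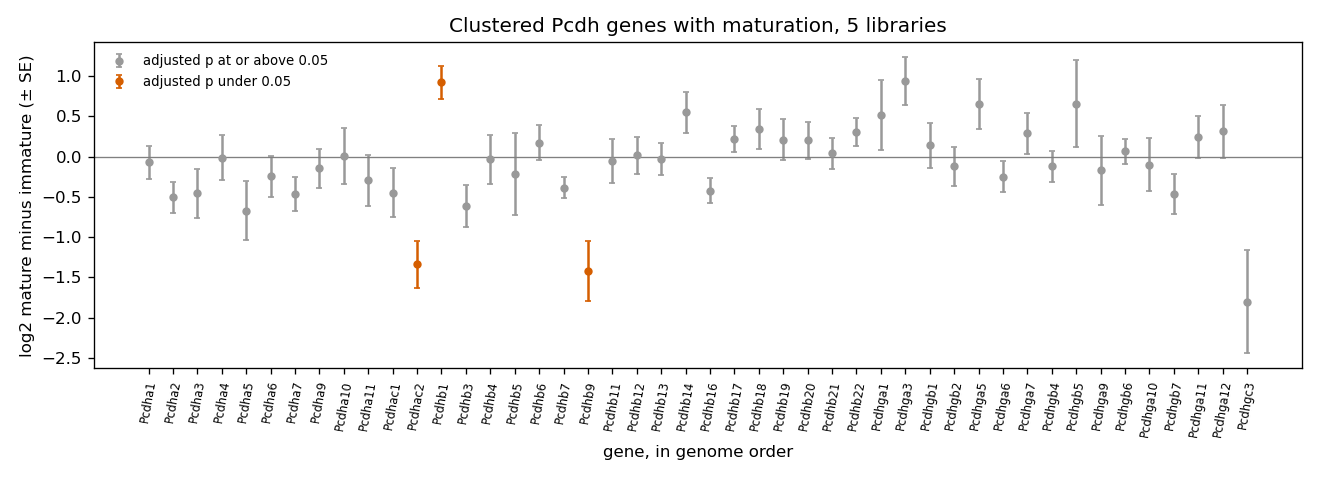
Log2 change of each clustered Pcdh gene tested, mature minus immature OSN-like cells (n = 5 libraries), genes in genome order. Points are edgeR estimates, error bars are SE, and orange marks the 3 genes past the adjusted threshold, Pcdhb1 at 0.92, Pcdhac2 at −1.34 and Pcdhb9 at −1.42.

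Most genes of the maturity lists changed. Of 14 olfactory transduction genes 13 rose, among them the adenylyl cyclase Adcy3 (1.9 log2, SE 0.285, adjusted p = 0.0084), the cyclic nucleotide channel subunits Cnga4 (1.87) and Cngb1 (1.58) and the chloride channel Ano2 (1.58). Of the mature OSN markers 11 of 12 rose, and all 8 immature OSN markers and all 5 neuronal precursor markers tested fell. These markers named the clusters, and Adcy3, Cnga4 and Ano2 are among them, so these changes are no independent evidence. Their camera calls were lost with an estimated correlation (adjusted p = 0.651 for transduction and mature markers and 0.206 for immature and precursor markers). Odorant and other chemoreceptor genes rose in 101 of 430 and fell in 4, a call that held with an estimated correlation (adjusted p = 0.0214). Both vomeronasal neuron markers tested fell (adjusted p = 0.334 with an estimated correlation).

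Genes that act on chromatin and neuronal wiring changed in both directions. In the DNA methylation and silencing list 3 of 8 fell, the methyltransferase Dnmt3a (−0.71) and the methylcytosine dioxygenases Tet1 (−1.36) and Tet3 (−0.84), and none rose (camera adjusted p = 0.0191, adjusted p = 0.715 with an estimated correlation). In the cohesin and CTCF list 3 of 11 rose, Ctcf (0.41), the cohesin subunit Rad21 (0.37) and Smc1a (0.19), and Pds5a, a cohesin regulator, fell (−0.21). In the axon guidance and adhesion list 6 of 21 rose, led by the ephrin Efna5 (1.09, SE 0.074, adjusted p = 0.00137) and the semaphorin receptor Plxna1 (0.95), and 4 fell, led by Nrp2 (−0.83) and Tenm4 (−0.85). Of 8 non-clustered protocadherins Pcdh11x rose (0.95) and Pcdh1 (−0.71) and Pcdh7 (−0.84) fell. Pcdh1 was at 0.05 where classes were taken by marker UMIs, and the call on Pcdh7 was lost without HS5inv (adjusted p = 0.0555) and without 3xCBS (0.066).

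In the list of genes flanking the Pcdh clusters 3 of 13 rose, the splicing gene Zmat2 (0.41), the complex I subunit Ndufa2 (0.59) and Taf7 of the general transcription machinery (0.51), and the histone deacetylase Hdac3 fell (−0.54). In the odorant receptor choice list 3 of 13 rose, the receptor transporters Rtp1 (0.65) and Rtp2 (0.85) and the chaperone Hspa5 (0.26), and the demethylase Kdm1a fell (−0.85). Rtp1 was also among the mature OSN markers that named the clusters, so its rise is no independent evidence. Rtp1, Rtp2 and Kdm1a changed most in HS5del (1.2, 1.57 and −1.68) and ac1pCBSdel (1.04, 1.38 and −1.45). In WT they changed by 0.33, 0.27 and −0.34, so their size depends on the library. The immature class itself differed, since cluster 13 held 72.7% of it in HS5del, 70.5% in ac1pCBSdel and 7.25% in WT. The libraries thus did not compare the same immature cells. Of 13 immediate early and dissociation genes 4 rose, among them Ier2 (1.13), Fosb (0.88) and Jund (0.38), and Btg2 fell (−1.33). Hmgn1 of the dorsal zone list fell (−0.72), and Nfix of the ventral zone list rose (0.80). Of the 35 genes named for maturation, 18 passed without each library in turn. Leaving out any of the 5 libraries ended the calls on Pds5a, Smc1a, Hspa5 and Hmgn1, with adjusted p up to 0.105, 0.167, 0.137 and 0.138. Leaving out any but WT ended those on Rtp1, Rtp2, Kdm1a and Jund (up to 0.106, 0.106, 0.132 and 0.0746), and any but HS5inv that on Taf7 (up to 0.0696). The calls on Ndufa2, Nfix and Ier2 were lost without 3xCBS (0.0545, 0.0538 and 0.0523) and that on Tenm4 without ac1pCBSdel (0.054).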

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

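Of the tests in this part, those chosen only after the result was seen were the other reference libraries and the cluster by cluster comparison for the Pcdha genes, the near-empty barcodes in HS5inv the Gap43 shares and the sex-linked genes for Pcdhac2, and the rule that set aside a brain list.

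The share of alternate Pcdha UMIs from Pcdha10, Pcdha11 and Pcdha12 was 4.84% in 3xCBS against 17.4% in WT. Other references did not settle whether the WT library was the source. The ratio of these genes over that of Pcdha1 to Pcdha3 was 0.22 against WT and at most 0.211 against HS5del or ac1pCBSdel. It was 0.85 against HS5inv, whose share was also low (6.07%). The HS5del value rests on 6, 2 and 2 UMIs of Pcdha10, Pcdha11 and Pcdha12, and ac1pCBSdel itself had a high share (36.4%). The tables argue against free RNA, with a ratio of 0.219 after the profile of near-empty barcodes was subtracted. Across mature clusters the highest 3xCBS share was 7.2% and the lowest WT share 10.0%, closer than the bound set in advance for ruling out the mix of clusters, whereas in the 5 clusters with enough UMIs in both libraries the 3xCBS interval lay below that of WT in 5. Genotype may lower these genes near the end of the array, as a hypothesis from 1 library per genotype, and the counting of reads in constant exons stays open as untested.

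Pcdhac2 stood at 31.9 CPM in HS5del and 33.3 in HS5inv against 9.27 in WT. Sustentacular-like cells express Pcdhac2, but their RNA, scaled by their markers, would bring 0.16 CPM to mature cells of HS5del, and near-empty barcodes would bring 5.01 CPM in HS5inv, which argues against both. For less mature neurons in the class, the share of immature RNA by Gap43, a gene of growing axons, could not decide. It was 5.42% in HS5del and 1.78% in HS5inv. The immature level of WT, 26.2 CPM, lies below both mature levels, so the needed shares of 134% and 142% could not be reached. Gap43 was also among the markers that named the classes. Immature cells at the WT level could not give these values. Those of HS5del and HS5inv themselves had 60.7 and 53.2 CPM. Less mature neurons stay open in HS5del, where Gap43 stood at 28.5 CPM in mature cells against 18.2 in WT. In HS5inv Gap43 was lower, at 9.36 CPM, and immature OSN markers had a median log2 ratio to WT of −0.47, with 6 lower and 2 higher. Both argue against less mature neurons in HS5inv, though these markers also named the classes. Over the median of the other 3 mutants the ratios were still 2.94 and 3.06, and 3xCBS and ac1pCBSdel stood at 10.9 and 3.59 CPM, which argues against the tagged strain of WT. Genotype may account for the higher Pcdhac2, with sex and collection open in HS5del, but in HS5inv sex is argued against by Xist at 257 CPM (216 in WT) and 0 UMIs of Ddx3y in both, and the titles call both OSN samples.

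Of 5 unnamed clusters, whose cells are in no comparison, 3 lay mostly in HS5del. Cluster 22, with Slc1a3 and Ntsr2 among its leading genes, held 3.91% of HS5del cells (3.28 to 4.63) and at most 0.455% of another library. Cluster 32, with Pcp4, Gad1 and Synpr among its leading genes, held 2.18% (1.71 to 2.74) and at most 0.506%, and cluster 35, with Igfbpl1, Meis2 and Dlx1 among its leading genes, held 2.55% (2.04 to 3.14) and 0 cells of each other library, where 3 counts of the total set a limit of up to 0.074% (HS5inv). The other clusters went otherwise: cluster 16 held 1.7% of HS5del and 1.31% of ac1pCBSdel, and cluster 33 held 1.76% and 3.56%.

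Brain tissue in the dissection, such as the adjoining olfactory bulb, is a candidate source, tested with 5 lists of 5 brain marker genes over all barcodes. The bound set in advance to argue against it, a list under 1.5 times another library, was met: the neuroblast list was at 0.852 of the next library. That bound was badly chosen, since Dcx gives 99.2% of that list in WT and immature OSN-like cells of WT express Dcx at 192 CPM. Of the other lists oligodendrocyte genes were 15.8 times the next library (2581 against 164 CPM), but astrocyte, GABAergic neuron and microglia genes were 2.3, 2.37 and 2.01 times, under the 3-fold that the explanation needed. Brain tissue and other sources cannot be told apart, since the sort on DAPI would remove neither. Of these clusters, ac1pCBSdel also held 27 cells of cluster 22 and 30 of cluster 32, but 0 of cluster 35.

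Among 35 genes tested for a library apart from the rest in the maturation change, Smc1a stood out, at 0.24 log2 in 3xCBS and 0.17 to 0.18 in the other 4, and chance alone picks about 1 gene in 20.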

How the results depend on the processing

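Tests chosen only after the data were seen were those with shared clusters weighted equally, with cells of highest doublet score left out, with single immature clusters and with subsets of libraries. Among ratios to WT 232 values stayed within their counting interval, 50 moved beyond it and 6 reversed, and no cause was tested unless stated. With WT as the reference, alternate Pcdha ranged from 0.139 to 0.221 in HS5del, 0.313 to 0.459 in HS5inv, 0.696 to 0.898 in ac1pCBSdel and 0.609 to 0.853 in 3xCBS, and Pcdhac2 from 3.14 to 5.43, 3.2 to 4.2, 0.354 to 0.416 and 1.07 to 1.38, so each kept its direction. The 5.43 for Pcdhac2 in HS5del comes from shared clusters with 24 to 50 HS5del cells each. Depth limits alternate Pcdha in HS5del (98 UMIs) and the C-type genes in ac1pCBSdel (7 UMIs of Pcdhac1 and 48 of Pcdhac2) and HS5del (34 and 176). No paired analysis of genotypes was possible because each has 1 library. Changes of the UMI limit or of doublets moved no group ratio beyond its interval.

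With the median of the other 3 mutants as the reference, which by construction follows those libraries, alternate Pcdha was at 0.255 in HS5del and 0.514 in HS5inv and reversed to 2.43 in ac1pCBSdel and 1.95 in 3xCBS. Pcdhac1 was at 2.75, 0.364 and 3.66 in HS5del, HS5inv and 3xCBS, and Pcdhac2 at 3.06 in HS5inv, 0.112 in ac1pCBSdel and, reversed, 0.34 in 3xCBS. Pcdhb was at 0.537, 1.5, 0.666 and 1.54 in HS5del, HS5inv, ac1pCBSdel and 3xCBS, and alternate Pcdhg at 0.81 and 0.903 (both reversed), 1.11 and 1.43.

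With shared clusters weighted equally, alternate Pcdha was at 0.313, 0.696 and 0.609 in HS5inv, ac1pCBSdel and 3xCBS, Pcdhac1 at 2.59 in HS5del, and Pcdhac2 at 5.43, 4.2 and 1.38 in HS5del, HS5inv and 3xCBS. In HS5del these clusters had 24 to 50 cells each and left out cluster 25, which held 69.9% of its mature cells. On the WT side clusters 1, 7 and 9, where shared, rested on 34, 24 and 28 cells. Pcdhb was at 0.718, 1.25, 0.755 and 1.22, alternate Pcdhg at 1.02, 1.24, 1.32 and 1.59 (HS5del, HS5inv, ac1pCBSdel, 3xCBS), and C-type Pcdhg at 0.576 in ac1pCBSdel. With mature cells taken by Omp, Gap43 and Gng8 UMIs, Pcdhac1 in HS5del reversed to 0.714, a choice of cells that rests on Omp, itself at 800 CPM there against 5658 in WT, and the cause was not tested. In that library alternate Pcdha was at 0.139, Pcdhb at 0.643, alternate Pcdhg at 1.03 and C-type Pcdhg at 1.32. In ac1pCBSdel alternate Pcdha was then at 0.825 and Pcdhb at 0.9.

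With the profile of near-empty barcodes subtracted, alternate Pcdha was at 0.459 in HS5inv and 0.853 in 3xCBS, Pcdhac1 at 2.6 in 3xCBS, Pcdhb at 1.73 and 1.76, alternate Pcdhg at 1.68 and 2.34 in HS5inv and 3xCBS, and C-type Pcdhg at 1.22 in HS5inv. The subtracted share was set by sustentacular markers and is too high in WT, HS5inv and 3xCBS, so these ratios carry that error. As a mean over cells, alternate Pcdha was at 0.751 in 3xCBS, and Pcdhb at 1.5 and 1.59 and alternate Pcdhg at 1.48 and 2.15 in HS5inv and 3xCBS. TMM factors gave 1.42 for Pcdhb in HS5inv, and a mitochondrial share under 5% gave 3.2 for Pcdhac2 in HS5inv.

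Shares of cells with an alternate Pcdha UMI follow the depth kept, by construction. In WT, HS5del, HS5inv, ac1pCBSdel and 3xCBS they were 63.2%, 12%, 30.7%, 35.8% and 49.3% without thinning and 31.7%, 6.13%, 13.5%, 28.2% and 24.2% at 4000 UMIs. At 1000 UMIs they were 9.34%, 2.76%, 8.7% and 6.93% in WT, HS5inv, ac1pCBSdel and 3xCBS. WT was highest and HS5del lowest at each depth.

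Counts of genes changed with maturation moved as well. Without each library in turn, which leaves fewer samples, 429 to 1355 genes were higher and 665 to 1239 lower in mature cells, and 0 to 4 clustered Pcdh genes passed. The higher count was 920, 766, 565 and 429 without HS5del, HS5inv, ac1pCBSdel and 3xCBS. Classes by marker UMIs gave 2642 higher, no filter on low counts 2399 and the libraries of mixed cells alone 2411. Cells thinned to 2000 UMIs, which leaves fewer genes tested, gave 543 higher and 561 lower, and the early immature cluster alone (2 libraries) 3102 and 2702. Keeping the 9 doublets gave 2059 higher and 1888 lower, within the 1.5-fold taken as unchanged, although so few cells differ. The cells were clustered anew in that setting, and immature OSN-like cells went from 455, 260, 151, 149 and 116 to 200, 230, 64, 120 and 52 in WT, HS5del, HS5inv, ac1pCBSdel and 3xCBS. The boundary between immature and mature cells is thus unstable, and whether it accounts for the change in counts was not tested. Clustered Pcdh genes past the threshold numbered 6 with DESeq2, 1 without the replicate block, 1 in thinned cells, 5 without cells of highest doublet score and 6 with the early immature cluster. Without the block 1058 genes were higher and 1224 lower. Of the genes named for maturation, 474 values across settings kept their call, 120 kept the direction without passing, and Pcdh1 reversed to 0.051 log2 with classes by marker UMIs.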

Other observations

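Of the tests in this part, those chosen only after the result was seen were the leading gene test and the counts of other splits of the samples.

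Clustered Pcdh genes also marked cells other than neurons in the libraries of mixed cell types. Olfactory ensheathing-like cells, the glia that wrap olfactory axons, had 67.3 CPM of Pcdhgc3 in HS5del (54.0 to 82.8) and 102 CPM in ac1pCBSdel (80.9 to 126), against 1.45 and 1.57 CPM in mature OSN-like cells. Their alternate Pcdhg genes stood at 112 and 141 CPM and their Pcdhb genes other than Pcdhb1 at 106 and 110 CPM, while alternate Pcdha had 3 UMIs in HS5del and 1 in ac1pCBSdel. Horizontal basal-like cells, the resting stem cells of the epithelium, had 12.3 and 14.4 CPM of Pcdhgc3 and 30.1 and 43.6 CPM of alternate Pcdhg. Sustentacular-like cells had 32.0 CPM of Pcdhac2 in HS5del (28.2 to 36.3) and 26.6 CPM in ac1pCBSdel (22.6 to 31.0), where mature neurons had 31.9 and 3.59 CPM. So Pcdhac2 in ac1pCBSdel was lower in mature neurons than in supporting cells of the same library, and in HS5del it was not.

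Pcdhb1 stood at 121 and 148 CPM in mature OSN-like cells of HS5del and ac1pCBSdel, 47.8 and 51.3 in immature OSN-like cells, 21.9 and 18.3 in sustentacular-like cells and 2.27 and 4.96 in ensheathing-like cells. Macrophage-like cells of ac1pCBSdel held more Pcdhb1 than its immature OSN-like cells, 86.5 CPM (68.2 to 108) against 51.3 (38.5 to 66.9), and 44.4 CPM of alternate Pcdha (31.6 to 60.7), where neutrophil-like cells of the same library held 5.22 and 5.69 CPM. The macrophage-like cells also had 60.3 CPM of the other Pcdhb genes and 52.4 of alternate Pcdhg. Mature OSN-like cells of that library had 102 and 72.3 CPM of these, and 87.1 of alternate Pcdha. So these groups stood in macrophage-like cells as in neurons, at lower levels. Doublets were not removed to any useful degree, and whether the RNA came from neurons was not tested. In HS5del macrophage-like cells held 22.2 CPM of Pcdhb1. In WT, Pcdhac2 stood at 26.2 CPM in immature OSN-like cells (22.6 to 30.3) and 9.27 in mature ones.

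A hypothesis of this re-analysis was that each neuron transcribes only part of the alternate Pcdha array, which has been described for single neurons in general. Among mature cells with at least 4 alternate Pcdha UMIs, the leading gene gave on average 64.2% of them in 203 WT cells and 67.5% in 120 3xCBS cells. There 100 draws at the summed composition of these same cells in each library gave 39.7% (at most 42.5%) and 44.3%. If single molecules were counted as several UMIs, other genes would show the same excess. In 100 sets of 12 genes matched on level, the median excess was 4.22 percentage points and the highest 10.1, against 24.5 for alternate Pcdha in WT, which argues against that as the main source. HS5del, HS5inv and ac1pCBSdel had 0, 19 and 11 such cells, too few for the test. The excess is consistent with unequal use of the array from cell to cell, and it does not show how many genes a neuron transcribes.

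For the maturation result the classes of a library are paired, and only 16 splits of the 10 sums part every library, too few for a share under 0.05. The real split gave 3068 genes and 3 clustered Pcdh genes, with as many in 1 of 16 splits, the real one, and the highest other gave 0 and 0. Of the 100 splits tried in all, the highest other gave 1832 and 3, and it does not part every library. The classes were also made by clustering the same cells, which favours the real split.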
